A study of Sus scrofa with 9 samples.

How the data were processed

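Gene expression was measured by RNA sequencing in outflow veins of arteriovenous fistulas (AVFs, surgical joins of an artery to a vein used for dialysis access) of pigs with a chronic kidney disease model. Per the labels, the fistula between carotid artery and jugular vein was made 28 days after kidney disease was induced, and the veins were taken 28 days later. Adipose-derived mesenchymal stem cells (MSCs) were placed on the outer wall of the vein in the MSC group, and control veins were untreated. The table held 9 libraries, 3 control and 6 MSC, each with a replicate number from its title. The names of control 2 (NT, F) and MSC 1 (Allo, M) carry tags that the labels do not explain. Y-linked reads, counted here on the listed sex-linked genes only, were 0 in control 2 and 85.1 CPM in MSC 1. Libraries were made from 0.5 µg of total RNA with a TruSeq kit, per the labels' protocols. The library names carry 9 different animal-like numbers and a flow-cell lane, but the labels do not state that each library is a separate animal. The p-values therefore measure the spread between these libraries, which may in part be technical.

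The values were RPKM (reads scaled to gene length and to the assigned reads of the library) for 30477 pig genes with Ensembl identifiers, as deposited by the authors; the unit was read per the file headers. The aligner, the counting tool and their settings were not given in the sources used here. The submitters' processing notes list the builds susScr11 and mm10, with no role given, so coordinates are printed as the deposited table gives them. Symbols came from the table, and 785 of the 14012 genes without one took a symbol from a gene name table. The deposited values, multiplied by gene length plus 1, were whole multiples of 1 step per library, which gave back read numbers. All values came within 0.01 of a whole number, the largest deviation being 4.56e-08. The recovered totals per library ran from 16939157 to 47417606 reads. In a gene of 2 kilobases, 1 read was worth between 0.0105 and 0.0295 RPKM, which sets the precision of low values. Intervals and floors of this kind cover counting error only. No read was listed on the 37 mitochondrial genes.

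The plan written before the data were examined named a count test for a count table, and limma-trend on log2(value + 1) for normalized values. Since the values were RPKM, the second was used. Genes were kept when they reached a count of 10, scaled to the median library, in at least 3 libraries and 15 reads in total, which left 17884 genes, 14584 of them protein-coding. RPKM values were divided by factors from the trimmed mean of M-values (trims 0.3 and 0.05), computed from the recovered reads. The model was fitted to log2(scaled RPKM + 1) with limma 3.58.1 in R 4.3.3, with all 9 libraries, no covariate and a variance prior that follows expression. Fold changes on this scale understate the change of low genes. Adjusted p-values are Benjamini-Hochberg values from limma, and 0.05 was the threshold. Means and SDs in the text are of scaled RPKM.

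The 26 gene lists (cell types, pathways and sample quality) were fixed before the data were examined. Of their 739 entries, 91 had no gene of that symbol in the table and 33 were below the filter; 16 genes stood on more than 1 list. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation, fry and an exact permutation of the mean z-score over all 84 splits of the libraries were alternatives. A list score is the mean z-score of its members in a library. The named genes were fixed by rule: the 10 genes with the largest change in each direction past the threshold, filled to 5 by the smallest p among genes with a mean of at least 50 reads; up to 4 members per list by smallest p; 14 genes of vein wall thickening and inflammation; and sex-linked genes. The rule took 125 genes, of which the text names 65. This narrowing was made after the values were seen, and after it was known how many genes changed sign between settings. It kept up to 4 members by smallest p for the list that held with an estimated correlation, up to 2 for other shifted lists and 1 for the rest, and 2 genes so kept were then left out of the text. ELN, RUNX2, SOX9, ISG15 and IFI6 were kept for their values. IL1B and MKI67 had no gene of that symbol in the table. Genes that overlap another listed gene may share its reads.

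The alternatives were other scaling factors, other filters, limma-voom on the recovered reads with and without sample quality weights, a robust prior, lane or replicate number in the model, subsets of libraries, each library left out in turn, a fold threshold of 1.5, and pseudocounts of 0.1 and 0.5. The MSC against control comparison was also tested on simulated reads, with 100 genes changed 4-fold and 100 changed 8-fold. With each gene's own spread, 21.0% of the 4-fold and 62.0% of the 8-fold changes passed among 17346 genes, and 14 other genes were called. With nothing changed, 0 of 17420 genes passed. Simulated genes vary independently, which real genes do not. No 2 libraries agreed within sampling noise; the smallest chi-square per degree of freedom between any pair was 79.8.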

Results

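The data were RNA-seq profiles of pig AVF outflow veins, 3 untreated (control) and 6 treated with adipose-derived MSCs at fistula creation, all harvested 28 days later. The comparison asks how MSC treatment alters gene expression in the vein that carries the fistula's flow. Depth ran from 16939157 reads in MSC 2 to 47417606 in MSC 5. The libraries differed in make-up within the groups. Small non-coding RNA took 53.3% of the reads in MSC 6 and 40.4% in control 2, against 6.75% to 16.4% in the others. MSC 2, the shallowest, had reads on 94.5% of genes and a median gene level of 1.21 RPKM, against 0.0823 to 0.376 in the other 8 libraries. MSC 5 correlated least with the rest (median r of 0.708 across genes, which are not independent replicates). Lane 7 held only MSC libraries, MSC 2, MSC 5 and MSC 6. The Y-linked genes EIF1AY and KDM5D had 1 read in all 3 controls together and 0 in MSC 3, while the other MSC libraries held 16.0 to 133 Y-linked CPM (reads scaled to library size). Over all genes listed on chromosome Y, the controls held 148 to 312 CPM, MSC 3 174 and the other MSC libraries 524 to 1214. Treatment and the presence of reads on EIF1AY and KDM5D therefore nearly overlapped, with MSC 3 as the exception.

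**Figure D1:**
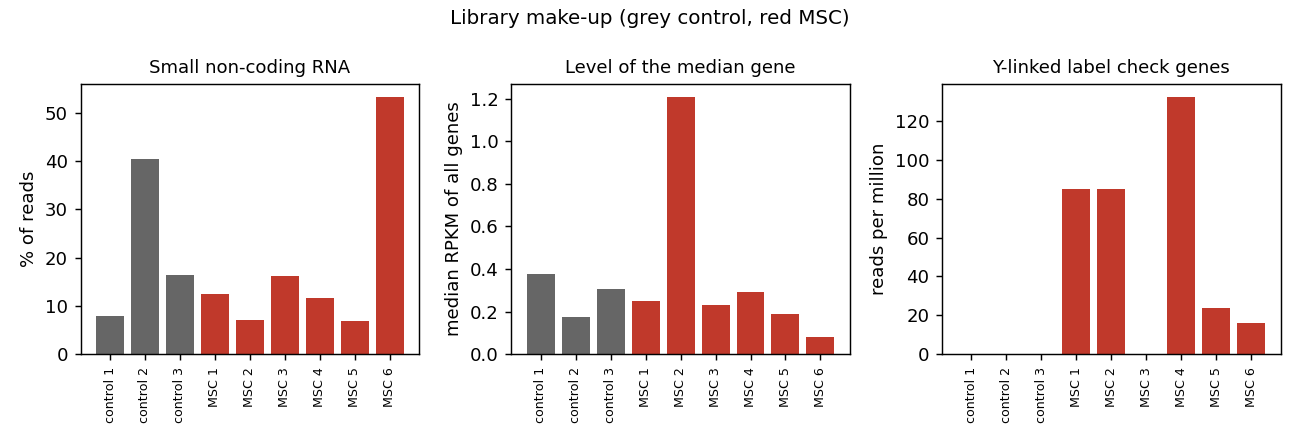
Make-up of each library: percent of reads on small non-coding RNA genes, RPKM of the median gene and Y-linked CPM, with 1 bar per library (grey control, red MSC). MSC 6 reached 53.3% small non-coding reads, MSC 2 a median of 1.21 RPKM, and Y-linked reads were at or near 0 in the controls and MSC 3.

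The genes that separated the groups most were higher for tissue factor, a protease and a growth factor antagonist, and lower for a B cell marker, but none passed the test with all libraries. F3, the tissue factor that starts coagulation (ENSSSCG00000022447, chromosome 4, 122826992 to 122837672), averaged 4.22 ± 2.91 RPKM (SD, n = 3) in controls and 32.8 ± 11.9 (SD, n = 6) in MSC veins. Its log2 fold change was 2.74 ± 0.43 (SE), with a limma adjusted p of 0.319; it overlaps ABCD3. Control 1 held the highest control value of F3 (7.58 RPKM). Without control 1 the control mean was 2.55 RPKM and F3 passed, with an adjusted p of 0.0379 from limma. F3 passed in 2 of 30 alternative settings, the other being limma-voom with sample quality weights, which leant on few libraries. PCSK6, a proprotein convertase, went from 3.73 ± 0.915 to 23.7 ± 10.7 RPKM, and ADGRD1, an adhesion receptor, from 3.52 ± 0.331 to 12.1 ± 2.07. FBP1, a gluconeogenic enzyme, and CHRDL1, an antagonist of bone morphogenetic proteins, had log2 fold changes of 2.34 each. On the lower side stood C11orf87 at −1.14 and CTXN3 at −1.28, both annotated as lncRNA with symbols from the gene name table, and ADAMDEC1 and ADAM7 at −3.16 and −2.91; ADAMDEC1 and ADAM7 overlap and may share reads. In each of these genes all 6 MSC libraries lay on 1 side of all 3 controls.

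Among 17884 genes, limma-trend called 0 higher and 0 lower in MSC veins at adjusted p of 0.05, the smallest being 0.319. At an unadjusted p under 0.05 there were 729 genes, 340 higher and 389 lower, against 894 expected by chance. limma-voom on the recovered reads called 0, with 809 at an unadjusted p under 0.05. With sample quality weights it called 1057 higher and 1112 lower. That fit leant on few libraries: control 3 had a weight of 8.26, against 1.09 and 1.61 for control 1 and control 2. MSC 1 and MSC 4 had weights of 3.05 and 3.13, and the other MSC libraries 0.0719 to 0.628. In 352 genes all MSC libraries lay above all controls and in 352 below, 3.94% of genes together against 2.38% by chance. That chance value is an average over splits of the libraries. Genes vary together, so a single split can lie far from it, and this count was not compared across splits. Without control 1, 24 genes were lower, TNFRSF17 and 2 other members of the B and plasma list among them, and F3 was higher (log2 fold change of 3.14, adjusted p of 0.0379); without MSC 3, 2 were lower and 1 higher; without MSC 2, 1 was lower. In lanes 5 and 6 alone, which hold both groups, 5 were higher and 2 lower.

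Genes of B and plasma cells were lower in MSC-treated veins, with the smallest camera p of the 26 lists. Of 22 measured members, 21 had a negative fold change, with a median log2 fold change of −0.61. MS4A1, which encodes the B cell antigen CD20, averaged 1.56 ± 0.631 RPKM (SD, n = 3) in controls and 0.279 ± 0.168 (SD, n = 6) in MSC veins. BLK, a B cell kinase, went from 1.31 ± 0.543 to 0.26 ± 0.205 RPKM. The plasma cell genes TNFRSF17, a survival receptor, and JCHAIN, the joining chain of secreted antibodies, went from 3.96 ± 3.26 to 0.117 ± 0.0885 and from 19.1 ± 15.5 to 2.25 ± 1.36 RPKM. MS4A1, BLK and TNFRSF17 were lower in all 6 MSC libraries than in any control. TNFRSF17 was at 0.318 RPKM in control 1, far below the other controls. JCHAIN was at 4.07 RPKM in control 1, below MSC 4 at 4.18, and its control mean was 11.1 RPKM without control 3. The lower level of TNFRSF17 and JCHAIN thus rested mainly on control 2 and control 3. MS4A1 (2.26 RPKM) and BLK (1.79 RPKM) instead had their highest value in control 1.

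The list passed camera with an adjusted p of 2.35e-19, with an adjusted p of 0.0226 with an estimated correlation and with fry at 0.0106. Adjusted over the list alone, 11 members passed, and over all genes 0 did with all libraries and 3 without control 1. The exact two-sided permutation p of the list score was 0.0119, the smallest that 84 splits can give, and 0.31 after adjustment over the 26 lists, below which 1 list alone cannot go. In lanes 5 and 6 alone the median was −0.63.

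**Figure D2:**
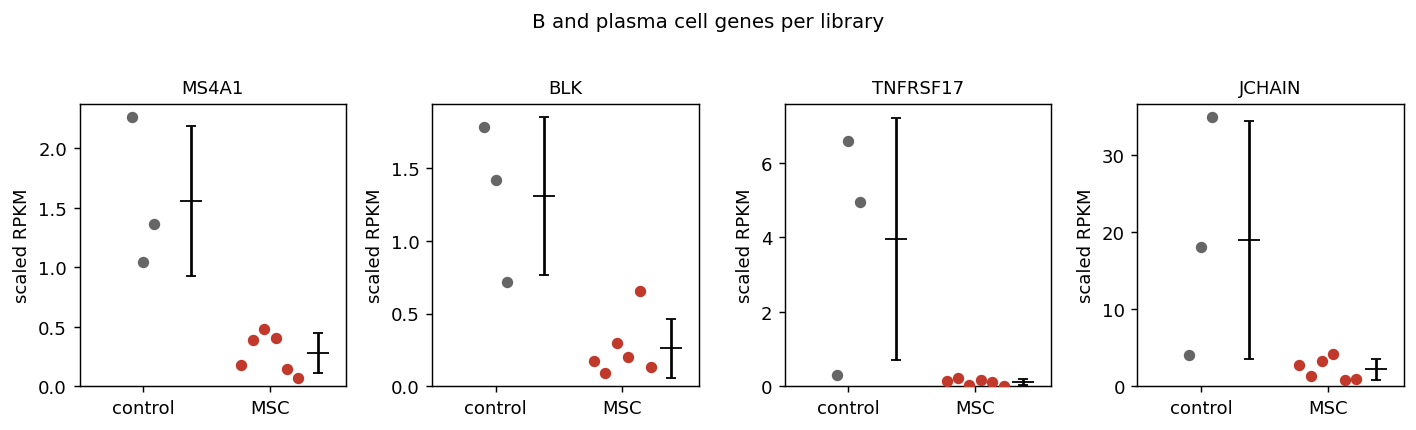
Scaled RPKM of MS4A1, BLK, TNFRSF17 and JCHAIN, with 1 point per library (grey control, n = 3; red MSC, n = 6) and the mean ± SD beside each group. TNFRSF17 averaged 3.96 RPKM in controls and 0.117 in MSC veins, and control 1 lay at 0.318.

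Other immune lists shifted downward with camera at the preset correlation. T and NK cell genes had 29 of 33 members with a negative sign and a median of −0.38 (adjusted p of 2.56e-07; adjusted p = 0.554 with an estimated correlation). KLRB1, a receptor of NK and T cells, went from 4.57 ± 2.23 to 1.27 ± 1.26 RPKM, and EOMES, a transcription factor of the same cells, from 0.7 ± 0.357 to 0.258 ± 0.107. The neutrophil list had a median of −0.23 (adjusted p = 0.554 with an estimated correlation), with MMP9 at −0.70. The macrophage list had a median of −0.18, with 16 of 26 negative (adjusted p = 0.76 with an estimated correlation). GPNMB, a glycoprotein of lipid-laden macrophages, averaged 219 ± 143 RPKM in controls and 39.7 ± 29.5 in MSC veins, and TREM2, a lipid-sensing receptor, 3.50 ± 0.983 and 1.35 ± 0.574. The peripheral nerve and glia list had a median of −0.17 (adjusted p = 0.554 with an estimated correlation), with SCN7A at −1.23. The control mean of SCN7A was 3.88 RPKM without control 1, against 6.70 with it. No member of these 4 lists passed over all genes or over its list alone. Leaving out 1 library at a time ended no call for T and NK genes. It ended that of the macrophage list without control 2, MSC 1, MSC 2, MSC 4 or MSC 5 (medians over the 9 libraries left out from −0.50 to −0.0222). The neutrophil call ended without control 1, MSC 1, MSC 2, MSC 4 or MSC 6 (−0.38 to −0.15), and the nerve call without control 1, MSC 1, MSC 2 or MSC 3 (−0.68 to −0.00318). With Y-linked reads as a covariate, which nearly coincide with treatment, the T and NK median was −0.0374 and that of macrophages 0.62, both with the direction of camera reversed, and that of neutrophils 0.0729. The control mean of GPNMB was 136 RPKM without control 1, and the MSC mean of KLRB1 0.781 without MSC 3. In lanes 5 and 6 alone the T and NK median was −0.09 and the macrophage median 0.08, the T and NK, neutrophil and macrophage lists did not pass (adjusted p from 0.211 to 0.912), and the nerve median was −0.77. MSC 3 had a T and NK score of 0.944, near that of control 2 at 0.96.

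Contractile smooth muscle genes shifted upward, with 23 of 26 members positive and a median of 1.38 (camera adjusted p of 1.74e-08, adjusted p = 0.554 with an estimated correlation). The highest value was in MSC 5 for 13 members and in MSC 6 for 11. ACTG2, a smooth muscle actin, averaged 11.8 ± 8.03 RPKM in controls and 425 ± 607 in MSC veins, with 695 in MSC 5, 1550 in MSC 6 and 3.79 in MSC 3. PGM5, a protein of muscle attachment sites, went from 3.27 ± 2.65 to 19.1 ± 10.2, and was above every control in all 6 MSC libraries. Adjusted over the list alone 1 member passed, and 0 did over all genes. ELN, the matrix protein elastin, averaged 87.3 ± 64.9 and 3431 ± 4368 RPKM, with 10881 in MSC 5, 6657 in MSC 6 and 177 in MSC 3. LTBP2 and MFAP5 encode proteins of elastic microfibrils. LTBP2 averaged 4.93 ± 3.56 RPKM in controls and 69.8 ± 70.9 in MSC veins, and MFAP5 had a log2 fold change of 2.29, with its highest level in MSC 3 (305 RPKM) and 32.0 RPKM in MSC 5, against 32.1 in control 1. Without control 1 the control means of ACTG2, PGM5, ELN and LTBP2 were 7.19, 1.75, 51.4 and 2.87 RPKM. The MSC mean of ACTG2 was 200 RPKM without MSC 6, and that of ELN 1940 without MSC 5. Without MSC 5 and MSC 6 the smooth muscle median was 0.59, in lanes 5 and 6 alone it was 0.42 with an adjusted p of 0.0761, and with Y-linked reads as a covariate 0.52 with 0.413.

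Another 6 lists shifted upward by camera. The cell proliferation list had 28 of 32 members positive and a median of 0.28 (adjusted p = 0.554 with an estimated correlation), with TPX2 at 0.50 and UBE2C at 0.76, and in lanes 5 and 6 alone it was 0.30. Its call was lost without control 1 (0.18, adjusted p of 0.0768), without control 2 and MSC 1 (0.20, adjusted p of 0.0839) and with no low-count filter (0.17, adjusted p of 0.158). Erythroid genes, 6 of 13 measured, had a median of 0.59 (adjusted p = 0.541 with an estimated correlation). HBB, the beta globin, was at 2.93 and AHSP, which stabilises alpha globin, at 0.62. MSC 6 held the highest value of 4 of the 6. The control mean of HBB was 5.21 RPKM without control 1, against 15.9 with it. Its MSC mean was 128 without MSC 6, against 195. AHSP averaged 15.1 reads, and its control mean was 0.0788 RPKM without control 1, against 0.217. The TGF-beta and BMP list had a median of 0.38 (adjusted p = 0.554 with an estimated correlation), with INHBA, an activin subunit, at 1.25 and LTBP2 as above. The vascular endothelium list had a median of 0.42 (adjusted p = 0.637 with an estimated correlation), with CLEC14A at 0.90 and MMRN1 at −1.40. Immediate early genes had a median of 0.22, with KLF4 at 0.78 and NR4A3 at 0.97, and skeletal muscle genes 0.20, with CASQ1 at 0.62 and CAV3 at 0.37 (adjusted p = 0.554 each with an estimated correlation). No member of these lists passed the test. MSC 5 held the highest value of 17 of 30 TGF-beta, 16 of 30 immediate early and 13 of 25 endothelial genes. Without MSC 5 these medians were 0.18, 0.12 and 0.16, and these lists and the skeletal muscle list (0.20) lost their call (adjusted p from 0.0769 to 0.127). TGF-beta also lost it without control 3 (0.35), MSC 1 (0.40) or MSC 6 (0.28), and immediate early genes without control 3 (0.19) or MSC 1 (0.22). Endothelium lost it without control 2 (0.15), MSC 2 (0.34) or MSC 3 (0.44), and skeletal muscle without MSC 2 (0.31). In lanes 5 and 6 alone the TGF-beta, endothelium, immediate early and skeletal muscle lists did not pass, with adjusted p from 0.148 to 0.912.

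The remaining 14 lists did not pass camera with all libraries. They were inflammatory mediators (median of 0.02, with CXCL14 at −1.17), fibrillar matrix (0.13, with MFAP5 at 2.29), matrix proteases (−0.06, with MMP13 at −0.91), hypoxia (0.00, with CA12 at −0.86) and interferon response (−0.00, with IFI35 at 0.65). The interferon call turned with the libraries: without MSC 3 the list shifted downward (median of −0.35, camera adjusted p of 0.00157), and in lanes 5 and 6 alone, which hold MSC 3, upward (0.84, adjusted p of 1.52e-07). It also shifted upward with lane as a covariate (0.67) and with the replicate block (0.48). The treatment term of both fits rests on fewer libraries, MSC 3 among them. Lane 7 holds only MSC libraries, and MSC 4, MSC 5 and MSC 6 share their replicate number with no control. In lanes 5 and 6 alone, oxidative phosphorylation genes (0.30, adjusted p of 2.91e-05) and inflammatory mediators (0.20, adjusted p of 0.0191) shifted upward too. These calls used the preset correlation. MHC class II genes had a median of 0.01, apoptosis genes −0.07, oxidative phosphorylation genes 0.13, and lipid metabolism genes 0.15; RFX5, GADD45A, SDHB and CPT1A led them at 0.41, −0.67, 0.55 and 0.71. The fibroblast list was at 0.31, with CD34 at 1.73, the lymphatic list at −0.44, with RELN at −1.23, mast cells at 0.12, with HPGDS at −0.29, and adipocytes at 0.02, with SLC7A10 at 0.87. The osteochondrogenic list had a median of 0.07, and 3 members passed adjusted over the list alone. A gene annotated as a pseudogene, which the gene name table matched to TNFRSF11B, was higher by 2.02, and the skeletal transcription factors RUNX2 and SOX9 were lower at −1.13 and −1.27. None of the 3 passed over all genes.

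**Figure D3:**
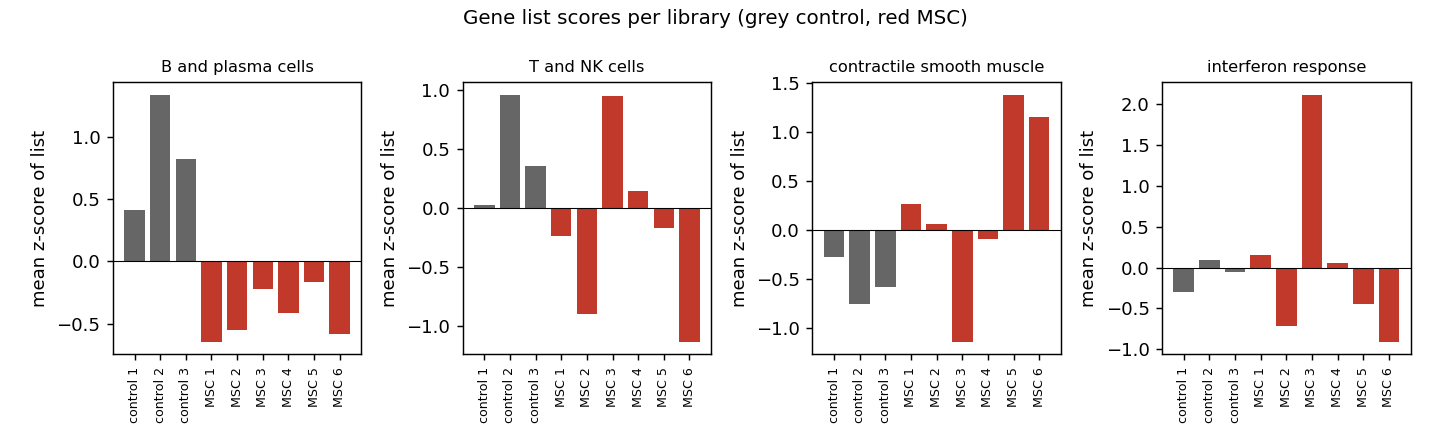
Mean z-score of 4 gene lists in each library (grey control, red MSC). The B and plasma score was above 0 in all 3 controls and below 0 in all 6 MSC libraries, the smooth muscle score was highest in MSC 5 and MSC 6, and the interferon score reached 2.12 in MSC 3.

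The genes fixed for vein wall thickening did not pass. CCL2, a monocyte attractant, averaged 22.2 ± 9.26 RPKM in controls (SD, n = 3) and 64.5 ± 44.3 in MSC veins (SD, n = 6). ACTA2, a smooth muscle actin, had a log2 fold change of 1.33 ± 1.04 (SE), and MYH11 averaged 32.1 ± 27.0 and 341 ± 417 RPKM. MYH11 averaged 16.7 RPKM in controls without control 1 and 193 in MSC veins without MSC 5, and stood at 11.4 in MSC 3, below every control. COL1A1 averaged 2581 ± 1710 and 5985 ± 8667, with 23153 in MSC 5 alone, and had a log2 fold change of −0.08 without that library. Its control mean was 1706 RPKM without control 2. FN1, VEGFA, HIF1A, TGFB1, MMP2, CD68 and TNF had log2 fold changes of 0.27, 0.49, −0.48, −0.37, −0.47, −0.58 and −0.18. Of the genes named here, CHRDL1, TNFRSF17, JCHAIN, GPNMB, LTBP2, HBB, MYH11, ACTA2, RUNX2, TNFRSF11B, CA12, RELN, RFX5, SLC7A10 and CAV3 also overlap another listed gene, so their reads are uncertain.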

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

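The tests of leukocyte share, lane 7, sex and small RNA, and the splits for the B and plasma list and for genes past the threshold, were chosen after the results they bear on were seen. Of 98 values tested in the 6 MSC libraries (7 library measures, 26 list scores and 65 genes), 12 held 1 library far from the other 5, where chance gives about 4.9; the controls were too few to test. MSC 3 stood above the others in its scores for interferon response (2.12, others at most 0.152), MHC class II presentation (1.45) and inflammatory mediators (1.15). MSC 5 stood above in matrix proteases (0.742), immediate early genes (1.05), peripheral nerve genes (0.998) and CXCL14 (4.66 on the log2 scale). MSC 6 stood below in EOMES (0.0694) and RUNX2 (0.842) and above in its share of small non-coding RNA (53.3%). MSC 2 stood above in CA12 (1.01) and in the level of its median gene (1.21 RPKM).

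The first pattern was the lower level of B and plasma cell genes in MSC veins. In 1 of the 84 splits, the real one, this list's camera p was as small (minus log10 p of 20.04, highest other 13.7), but the list was singled out by that p, and in 13 of the splits some list of the 26 had a p as small (highest other 29.9), so chance is not excluded over the lists. A lower share of all leukocytes was weighed with the B and plasma score minus the mean of the T and NK, macrophage and neutrophil scores. It was 0.552 ± 0.391 (SD, n = 3) in controls and −0.276 ± 0.419 (n = 6) in MSC veins (exact two-sided permutation p of 0.0238). This cannot decide the question, because a list picked as the most shifted of the 26 favours such a difference. Control 1 (0.119) and MSC 2 (0.101) nearly met. The lowest value, −1.06 in MSC 3, came with high T and NK (0.944) and macrophage (1.32) scores of that library. Lane 7 is argued against, since the median was −0.63 without it. Sex stays open: with Y-linked reads as a covariate the median was −0.46 (camera adjusted p of 1.12e-08; adjusted p = 0.105 with an estimated correlation), but 53.2% of the MSC weight in that fit lay on MSC 3, the only MSC library without such reads, and that 1 library lay below all controls.

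The second pattern was the high smooth muscle score of MSC 5 and MSC 6. Their shares of small non-coding RNA lay at opposite ends (6.75% and 53.3%), and with protein-coding reads alone the lower of both scores still lay 0.251 above the highest of the other 7 libraries. This argues against small RNA and its scaling as the whole cause, though the protein-coding set probably still held some such reads. ARHGEF39, annotated as protein-coding, and the ribozyme gene RNase_MRP each held 2.16% of the reads in MSC 6. The lead of MSC 6 shrank, however. Its score was 1.15 with all reads and 0.652 with protein-coding reads alone. The highest of the others, MSC 1, went from 0.266 to 0.401. Scaling may therefore account for part of the lead of MSC 6. A lane effect cannot be told apart, because lane 7 holds only MSC libraries; MSC 2, on the same lane, scored 0.202 below the highest library of lanes 5 and 6 (difference −0.202), but 1 library excludes nothing. A larger share of vein wall muscle in these samples may also apply and was not tested.

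The third pattern was the floor of silent genes in MSC 2. Over 3409 autosomal protein-coding genes with a mean under 0.05 RPKM in the other 8 libraries, MSC 2 had a median of 0.421 RPKM and the others at most 0.0148. If genomic DNA was the source, silent X-linked genes in a library with Y-linked reads would lie far below autosomal ones. The ratio was 0.73 over 225 X-linked genes (95% bootstrap interval 0.596 to 0.993), which spans the bound of 0.8 between both outcomes. The test therefore cannot decide whether genomic DNA made up the floor, in whole or in part. No biological explanation was tested.

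Across the 84 splits, 20 gave at least the 729 genes at an unadjusted p under 0.05 (highest other 6573) and 13 at least 12 shifted lists (highest other 17), so chance is not excluded for these counts. For the 0 genes past the limma threshold the splits decide nothing, since all 84 must give at least 0 (highest other 1219). The split of control 2, MSC 5 and MSC 6 against the rest called 1219 genes, which points to a structure of the samples other than treatment.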

How the results depend on the processing

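Pseudocounts, protein-coding genes only, the subsets without pairs of named libraries and the covariates of small non-coding and Y-linked reads were chosen after seeing the data. The limma count of genes past the threshold stayed at 0 under the other scalings, filters and pseudocounts (451 to 850 at an unadjusted p under 0.05), and scaling moved the median of all genes by at most 0.0647. The B and plasma median ran from −1.51 to −0.46. The list passed in 28 of 29 settings with list tests, all but the exact permutation. That test gave an adjusted p of 0.31 (median −0.61), below which 1 list alone cannot go. Apart from the estimated correlation, fry and the permutation, these settings repeated camera at the preset correlation of 0.01. The correlation estimated for this list was 0.117. With Y-linked reads as a covariate, camera with an estimated correlation gave an adjusted p of 0.105. Elsewhere results moved as follows, and the cause was not tested, apart from the smaller number of libraries in subsets. Quality weights gave 1057 higher and 1112 lower genes, with weights from 0.0719 for MSC 5 to 8.26 for control 3. Lanes 5 and 6 alone gave 5 higher, 2 lower and 7 lists, 3 of them not called with all libraries (interferon 0.84, oxidative phosphorylation 0.30, inflammatory mediators 0.20). Of lists not called with all libraries, interferon (medians up to 1.35), lymphatic and oxidative phosphorylation genes passed in 7 settings each with their direction kept, inflammatory mediators in 3, matrix proteases in 2 and MHC class II in 1. Without control 2 and MSC 1, whose names carry extra tags, limma called 0 genes (279 at an unadjusted p under 0.05) and 9 lists shifted; without MSC 2 and MSC 5, 2 were lower; without MSC 5 and MSC 6, 7 lists shifted. Without each library in turn, 0 to 1 gene was higher, 0 to 24 lower (24 without control 1), and 7 to 11 lists shifted (7 without MSC 1). The B and plasma, T and NK, smooth muscle and erythroid lists passed in all 9 of these; the other 8 lists lost their call in 1 to 5. An estimated correlation left 1 list, fry 1 and the exact permutation 0. The title numbers did not pair the samples (correlations of 0.217, −0.523 and −0.141), and the replicate block gave 0 genes with limma (803 at an unadjusted p under 0.05) and 8 lists, with HIF1A at 0.17 and COL1A1 at −0.48. MSC 4, MSC 5 and MSC 6, without a control of the same number, add nothing to the treatment term of that block. With lane as a covariate, the same holds for the libraries of lane 7. Of the 65 genes named, 9 changed sign in some setting, 25 times in all; of all 125 genes the rule took, 22 did, 50 times in all, so the named genes give too stable a picture. The named ones changed with quality weights (SLC7A10 −0.34, VEGFA −0.31, HIF1A 0.12, COL1A1 −0.55), lane as a covariate (VEGFA −0.20, HIF1A 0.21, HPGDS 0.0638, COL1A1 −0.52), lanes 5 and 6 alone (VEGFA −0.15, HIF1A 0.15, HPGDS 0.27, COL1A1 −0.54, FN1 −0.0859), without MSC 5 and MSC 6 (HIF1A 0.0978, HPGDS 0.0515, COL1A1 −0.54), and Y-linked reads as a covariate (CASQ1 −0.18, ACTA2 −0.34, CD68 0.71, HPGDS 0.43, FN1 −0.22). The direction of camera changed for lists, at these medians, with lane as a covariate (skeletal muscle −0.0136), lanes 5 and 6 alone (macrophages 0.0799, skeletal muscle −0.00551), without control 2 and MSC 6 (endothelium 0.11), without MSC 2 and MSC 5 (macrophages 0.0218) and Y-linked reads as a covariate (macrophages 0.62, T and NK −0.0374). Without single libraries the interferon median ran from −0.35 (without MSC 3) to 0.24, and COL1A1 from −0.12 (without control 1) to 0.995 (without control 2), with −0.08 without MSC 5. DESeq2, a surrogate variable and the edgeR fits were planned for a count table and left out when the values proved to be RPKM; the recovered reads would have allowed them, and only limma-voom was run on those. Depth limits low genes to steps of 1 read.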

Other observations

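The genes and counts of this part were chosen after the results were seen; the fits without control 1 and with lanes 5 and 6 alone were planned. The immunoglobulin segment genes were high in control 2 and control 3, but not in control 1. All 5 that were tested (4 variable and 1 constant) had lower fitted values in MSC veins, by 6.90-fold to 43.9-fold. With all libraries none passed, the smallest limma adjusted p being 0.395. Without control 1, which leaves only control 2 and control 3, the fitted values of these 5 were lower by 17.8-fold to 165-fold. All 5 passed (largest limma adjusted p of 0.0153), as did a further variable segment not tested with all libraries. The control left out was the only one at the level of the MSC libraries, which favours such a result. Their summed level was 2141 RPKM in control 2, 1076 in control 3 and 35.8 in control 1, against 4.07 to 37.3 in the MSC libraries. Control 1 lay inside the range of the MSC libraries. Variable segments resemble each other, so reads may be shared between them; in lanes 5 and 6 alone the B and plasma median was −0.63.

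The interferon response was high in a single treated vein. In MSC 3, 32 of the 34 measured interferon genes had their highest level of all 9 libraries. ISG15, a ubiquitin-like modifier, stood at 151 RPKM in MSC 3 and at 1.39 to 13.5 elsewhere, and IFI6 at 609 against 20.8 to 132. MSC 3 also held the highest level of 18 of 26 macrophage genes, 18 of 34 inflammatory mediators and 8 of 11 MHC class II genes. No cause was tested.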
